A study of Mus musculus with 6 samples.

How the data were processed

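RNA was sequenced from 6 libraries of fluorescence-sorted mouse brain cells of the C57BL/6 strain. Per the labels' protocols, total RNA and DNA were isolated together from the same cell pellets with on-column DNase treatment, RNA quality was assessed on a Bioanalyzer, and libraries followed standard Illumina protocols. How reads were counted, whether counting used the strand and how the values were scaled is not given in the sources used here. Per the submitters' processing notes, BWA, DESeq2 1.2.5 and the mm10 build were used, with no role or order stated.

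The authors deposited 1 file per library with log2 expression values for 24385 RefSeq transcripts, per the file headers. Libraries were not combined with each other, and the labels do not say whether a library came from pooled animals. The deposited log2 values were already on a common scale: the median deviation of each library from the row means lay between -0.0056 and 0.0023. On the linear scale 1.95% of values lay within 0.01 of a whole number, against 2.0% by chance, so whole reads could not be recovered and the depth of each library is unknown. Whether the values were divided by transcript length is not given in the sources used here, so levels of different genes are compared only loosely. The lowest value in any library was 1.24, there was no 0, and no mitochondrially encoded row was present.

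In 49 rows the gene symbol was a number of the kind a spreadsheet makes from a date, and 48 of these were named through their RefSeq accession from a gene table of assembly GRCm38.p6. The rows then held 18163 genes, of which 3741 had more than 1 transcript row. Each gene was represented by the transcript row with the highest mean over the 6 libraries. Transcripts of 1 gene share exons, and genes with near-identical copies (the globins, Hspa1a and Hspa1b, H2-K1 and H2-D1), overlapping genes and antisense genes are uncertain, because the counting is not known. Coordinates are those of the deposited rows in mm10. Of 22690 rows linked by accession to a GENCODE M21 transcript, 22512 overlapped it on the same chromosome and strand, 8424 had a start 1 base below the annotated one and 770 the same start. Starts were therefore read as counted from 0 and are given counted from 1.

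Libraries were grouped by their labels into 3 of sorted Pdgfra::GFP+ cells of postnatal day 2 (P2) and 3 of sorted Plp1-GFP+ cells of postnatal day 18 (P18). The single comparison is P18 minus P2. An edgeR test, chosen in advance for the case of counts, was not run. Because the values are log2, limma 3.58.1 in R 4.3.3 was fitted to them as deposited, with no pseudocount, group as the only term, and a trended and robust empirical Bayes variance. A gene was tested if its value was at least 7 in at least 3 libraries, which kept 15545 genes. P-values were adjusted by Benjamini-Hochberg over the tested genes, two-sided, with a threshold of 0.05. Values are given as log2 means ± SD with n = 3 per group, and log2 fold changes with their standard error (SE). A level in ppm is a gene's share of the library's linear total (2 to the power of each value, summed over genes), in units of 1e-06. It replaces the planned share of counts in the rule for named genes.

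Before the data were examined, 27 gene lists were fixed, among them markers of other brain cell types. Each list was tested with limma's camera at a preset correlation of 0.01, which compares a list with all other tested genes, adjusted over the 27 lists. Camera with an estimated correlation and fry served as alternatives. For each list the count of members passing the gene test is given with the adjustment over all genes and with p-values adjusted over the list alone. The named genes were also fixed by rule. They are Pdgfra and Plp1 as a check of the labels; the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 5 ppm and no overlap between the replicates of the groups; in each list, the 3 largest changes in the main direction with a mean of at least 1 ppm and the largest in the other; every DNA methylation gene; and, for other cell types, the most abundant marker in each group. Genes named outside this rule, where a count covered few genes, were chosen after their values were seen.

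The fit was tested on simulated data for this comparison (3 against 3, 15545 genes, 200 changed genes in each of 5 draws). It recovered 5.37% of changes of 0.5 on the log2 scale, 78.5% of changes of 1 and 100% of changes of 2, and 1.61% of its calls were false. In the real data 8453 genes passed, far more than the 200 simulated, so the adjustment is less strict there. Genes were drawn independently, without differences between libraries that genes share. These shares therefore check the fit and do not carry over to the real data. Transcript length and GC content came from GENCODE M21 by accession and were found for 95.8% of tested genes. A length correction subtracted, within each library, a lowess trend (span 0.3) of the deviation from the row mean on log2 length. The alternatives chosen in advance were median-ratio, upper-quartile and library-total scaling, no filter, a floor of 1 ppm, a replicate block, scaling without the 50 most abundant genes, pseudocounts of 0.1 and 5, and leaving out each library. A pseudocount of 1, planned for the main fit to normalized values, was run as an alternative. Chosen after seeing the data were a pseudocount of 100, a filter at 9, the mean of a gene's transcripts, every transcript as a row, a variance without trend, quantile normalization and the length correction. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.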

Results

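Gene expression was profiled in 2 stages of the mouse oligodendrocyte lineage, the cells that form myelin in the brain. At postnatal day 2, 3 libraries were made from sorted Pdgfra::GFP+ cells, which are oligodendrocyte progenitor cells (OPCs), dividing precursors marked by the receptor gene Pdgfra. At postnatal day 18, 3 libraries were made from sorted Plp1-GFP+ cells, which are oligodendrocytes marked by the myelin gene Plp1. The series characterises DNA methylation in this lineage, and its RNA arm asks which genes differ between the stages. Age, cell stage and reporter change together, so the comparison does not separate them. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Each library held values for 18163 genes, and its depth is unknown because only scaled log2 values were used. The mean linear total of the P18 libraries was 1.55 times that of the P2 libraries. The 50 most abundant genes held 11.6% to 12.6% of the total at P2 and 26.2% to 27.6% at P18.

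The genes behind the reporters served as a check of the labels rather than as findings, since the cells were sorted on them. Pdgfra is also in the list of OPC markers and among the largest falls, and Plp1 is in the list of myelin genes. The counts and tests of these lists therefore include a gene used for the sort. Pdgfra (mm10 chromosome 5, 75152291 to 75198204) was at 16.29 ± 0.36 (SD, n = 3) in the P2 libraries and 9.27 ± 0.02 (n = 3) at P18. Plp1 (chromosome X, 136822836 to 136837742) was at 20.07 ± 0.07 (n = 3) at P2 and 23.16 ± 0.42 (n = 3) at P18. It was the most abundant gene in every library, with 1.08% to 1.2% of the linear total at P2 and 4.94% to 9.32% at P18.

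Between the stages, 20 of 20 OPC markers, 23 of 25 genes each of S phase and of G2 and M phase, and 19 of 24 receptor genes for glutamate and GABA fell. Of the genes of myelin 27 of 30 rose, of cholesterol synthesis 19 of 21, and of sphingolipid and fatty acid synthesis 16 of 21. None of these lists passed with an estimated correlation between genes (camera adjusted p = 0.181 to 0.268). The largest rises included Opalin, a myelin membrane glycoprotein gene, which was 81.0-fold higher at P18 (log2 fold change 6.34, SE 0.31, limma adjusted p = 7.4e-06), and Mal, a proteolipid gene of compact myelin (5.64, SE 0.24). Efhd1 (6.69), Cryab, which encodes a small heat shock protein (6.13), Gm13293 (6.07), Aspa, the aspartoacylase gene (6.03), Ndrg1 (5.68), the channel genes Hcn2 (5.53) and Kcna1 (5.06) and the growth factor gene Fgf1 (5.17) completed the 10 largest. The largest falls were C1ql1 (-7.36, SE 0.22), Pdgfra (-7.01), the growth factor gene Igf2 (-6.88), the imprinted RNA H19 (-6.74), Sfrp2 (-6.64), Spry4, which encodes an inhibitor of receptor tyrosine kinase signalling (-6.58), Sstr1 (-6.58), 3110035E14Rik (-6.54), Cd248 (-6.38) and Chst11 (-6.32). The size of some of these changes depends on the processing, though their calls were kept. Over the alternatives Sfrp2 (mean 4.15 at P18) ran from -7.27 to -3.98, Cd248 from -7.01 to -4.44 and Gm13293 from 4.17 to 6.99.

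Many tested genes changed: 8453 of 15545 (54.4%) passed the limma test, 4339 higher and 4114 lower at P18. Changes of at least 2-fold numbered 5153, of which 2255 were rises and 2898 falls, and changes of at least 8-fold 185 rises and 712 falls. The balance of directions rests on the scaling: 51.3% of calls were higher with the deposited scaling, 17.9% (1789 higher, 8184 lower) when each library was scaled to its linear total, and 30.2% (2636 higher, 6095 lower) when the 50 most abundant genes were left out and the rest scaled to their total. These scalings moved the median log2 fold change of all tested genes from 0.03 to -0.60 and -0.33. Among the named genes, scaling to the linear total ended the calls of Cdkn2d, Rbl2, Zfp536, Grin2c, H2-D1, Ctss, Ly6a and Prx, all rises with the deposited scaling, whose log2 fold changes became -0.18 to 0.85. Leaving out the 50 most abundant genes ended the same calls. Upper quartile scaling ended those of Zfp536 (adjusted p = 0.0517), Grin2c (0.0564) and Ctss (0.0578), median-ratio size factors that of Zfp536 (0.0501), and the length correction those of Ctss (0.0629) and Ly6a (0.1115).

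**Figure D1:**
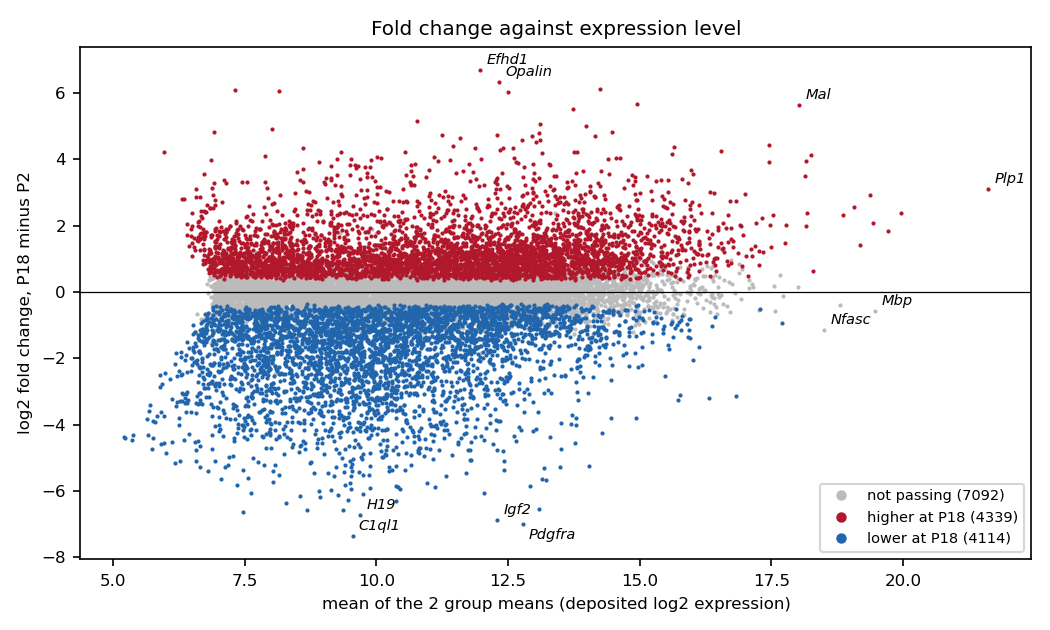
Each point is 1 of 15545 tested genes, with the mean of the 2 group means of the deposited log2 expression on the x axis and the log2 fold change (P18 minus P2) on the y axis. Red points (4339) were higher and blue points (4114) lower at P18 by the limma test, and grey points (7092) did not pass; falls reach -7.36 (C1ql1) and rises 6.69 (Efhd1).

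The libraries of a group were not equally alike. Pearson correlations across genes were 0.993 to 0.994 among the P2 libraries and 0.993 between P18 replicates 2 and 3, but 0.969 and 0.978 between P18 replicate 1 and these. Across genes, which are not independent replicates, the difference of P18 replicate 1 from the mean of the other 2 correlated with transcript length (Spearman rho = 0.495) and hardly with GC content (rho = -0.07). Its median ran from -0.65 in the eighth of genes with the shortest transcripts to 0.49 in the longest. Libraries that did not stand apart also differed with length: rho was -0.44 for P2 replicate 1 minus replicate 3 and -0.31 for P18 replicate 2 minus replicate 3. The log2 fold change itself had a rho of -0.16 with length.

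**Figure D2:**
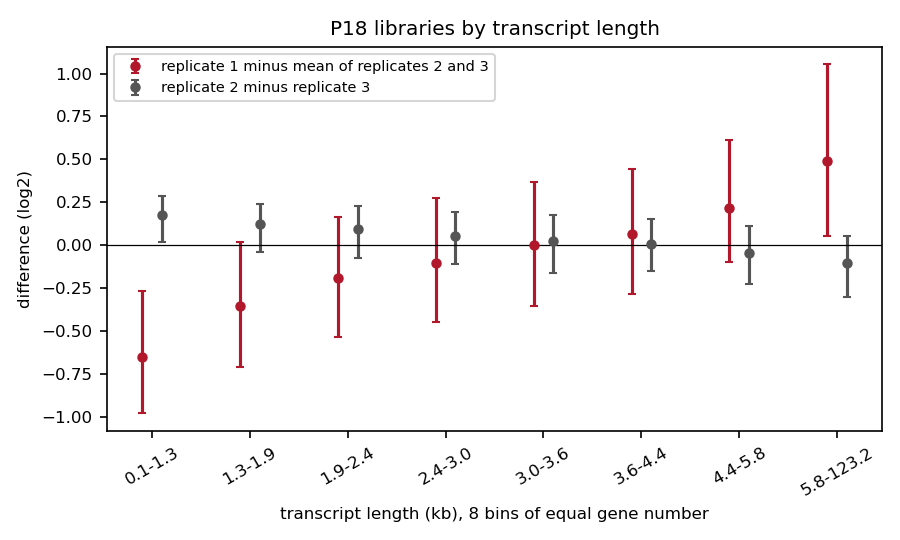
Transcript length in 8 bins of about equal gene number (x axis, kb) against the log2 difference between P18 libraries (y axis). Points are medians and bars the interquartile range over the genes of a bin; replicate 1 minus the mean of replicates 2 and 3 (red) runs from -0.65 to 0.49, and replicate 2 minus replicate 3 (grey) from 0.18 to -0.10.

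Progenitor markers fell together. All 20 tested OPC markers were lower at P18, with a median log2 fold change of -5.08 (camera adjusted p = 2.4e-12, adjusted p = 0.181 with an estimated correlation; 20 also with p-values adjusted over the list alone). Cspg4, the NG2 proteoglycan gene, fell from 15.06 ± 0.30 to 9.01 ± 0.14 (n = 3 each; -6.05, SE 0.19), and Cacng4 by 6.20 on the log2 scale. Of 16 markers of newly formed oligodendrocytes, 12 fell and none rose (median -2.33, camera adjusted p = 5.7e-05, adjusted p = 0.35 with an estimated correlation; 13 lower adjusted over the list alone). The largest falls were in Bmp4 (-5.22, SE 0.16), Neu4 (-4.70) and Mycl1 (-4.58). The members that did not pass were Enpp6 (-0.71), Rras2 (-0.18), Cnksr3 (-0.97) and Kif19a (-1.28). P18 replicate 1 held higher values of the newly formed markers than the other P18 libraries, by a median of 0.84, and 15 of the 16 passed without it.

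Most myelin genes rose. Of 30 myelin and mature oligodendrocyte genes, 27 were higher at P18 and none passed as lower (median 3.98, camera adjusted p = 2.4e-12, adjusted p = 0.218 with an estimated correlation; 27 adjusted over the list alone). Besides Opalin, Cryab and Aspa, Mog rose by 4.45, Mag by 2.07 and Cnp by 1.83 on the log2 scale. The P2 libraries already held some myelin transcripts at high levels, with Plp1 at 11511 ppm (parts of the linear total in units of 1e-06), Mbp at 9363, Cnp at 4798 and Mag at 3636. Opalin (6.04 ppm), Aspa (7.56) and Cryab (24.7) were low there. The 3 members that did not pass were Mbp, Nfasc and Myrf. Mbp (chromosome 18, 82554463 to 82585637), which encodes myelin basic protein, was at 19.76 ± 0.23 at P2 and 19.18 ± 0.88 at P18 (n = 3 each; -0.58, SE 0.42, adjusted p = 0.273). Nfasc, the neurofascin gene, had -1.15 (SE 0.57, adjusted p = 0.123) and Myrf, a transcription factor gene of myelination, 0.35 (SE 0.24, adjusted p = 0.248). Whether Mbp and Nfasc were called depends on P18 replicate 1 and on the scaling. Without replicate 1 both fell, Mbp by 1.08 on the log2 scale (adjusted p = 0.00013) and Nfasc by 1.88 (adjusted p = 1.7e-07). Quantile normalization of all libraries, chosen after seeing the data, gave -2.02 for Mbp (adjusted p = 0.0039) and -2.59 for Nfasc (adjusted p = 0.0031). Scaling to the linear total gave -1.22 for Mbp (adjusted p = 0.0419) and -1.79 for Nfasc (adjusted p = 0.0329), and turned Myrf to -0.29 (adjusted p = 0.353).

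Most genes of lipid synthesis rose as well. Of 21 tested cholesterol synthesis genes, 19 rose and none fell (median 1.51, camera adjusted p = 3.5e-07, adjusted p = 0.268 with an estimated correlation; 19 adjusted over the list alone). Hmgcs1, the HMG-CoA synthase gene, rose by 2.00 on the log2 scale (SE 0.16), Sc5d by 2.14 and Sc4mol by 2.09. Acat2 (0.36) and Srebf2 (0.30) did not pass. Under scaling to the linear total 16 cholesterol synthesis genes rose (median 0.87). Of 21 genes of sphingolipid and fatty acid synthesis, 16 rose and 2 fell (median 1.31, camera adjusted p = 4.6e-05, adjusted p = 0.181 with an estimated correlation; the same counts adjusted over the list alone). Cers2, a ceramide synthase gene (2.76), Fa2h, the fatty acid 2-hydroxylase gene (2.74), and Degs1 (2.63) rose most. The 2 that fell were the desaturase genes Fads2 (-2.76, SE 0.20) and Fads1 (-1.62, SE 0.23). Under scaling to the linear total 13 genes of sphingolipid and fatty acid synthesis rose and 3 fell (median 0.68).

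Most genes of cell division fell. In S phase, 23 of 25 genes were lower and none higher (median -1.38, camera adjusted p = 1.7e-07, adjusted p = 0.268 with an estimated correlation; 23 adjusted over the list alone), led by Rrm2 (-4.28), Mcm6 (-3.52) and Mcm5 (-3.06). Pcna (0.46, adjusted p = 0.188) and Ccne2 (-0.36) did not pass, and without P18 replicate 1 one S phase gene passed as higher. In G2 and M phase, 23 of 25 were lower (median -3.31, camera adjusted p = 3.8e-12, adjusted p = 0.268 with an estimated correlation; 24 adjusted over the list alone). Ccnb1, the cyclin B1 gene, fell from 12.30 ± 0.32 to 6.75 ± 0.44 (n = 3 each; -5.54, SE 0.26), with Ccna2 (-4.79) and Aurkb (-4.62) next, while Cenpe (-0.43) and Kif23 (-0.61) did not pass. The 11 tested cell cycle inhibitors went both ways, 4 higher and 3 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.873), with a median of 0.10, a mean of -0.31, and a median of -0.53 under scaling to the linear total (1 higher, 6 lower). Gas1 (-4.89) fell and Ccng2 (1.43) and Cdkn1b (0.64) rose. Calls of Cdkn2d (1.03) and Rbl2 (0.82) were both lost without P2 replicate 2 (adjusted p = 0.0586 and 0.0725), without P2 replicate 3 (0.0767 and 0.105) and without P18 replicate 3 (0.0719 and 0.0729), and that of Rbl2 also without P2 replicate 1 (0.112).

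Among the DNA methylation genes, Dnmt1 and Uhrf1, which act in maintenance methylation, were lower at P18. They were not tested as a set. Dnmt1 (chromosome 9, 20907206 to 20952979), the maintenance methyltransferase gene, fell from 13.67 ± 0.26 to 12.14 ± 0.46 (n = 3 each; -1.53, SE 0.26, adjusted p = 0.0020), a level 2.89-fold lower. Uhrf1 (chromosome 17, 56303337 to 56323486), whose protein brings DNMT1 to replicating DNA, fell by 2.72 on the log2 scale (SE 0.22, adjusted p = 5.2e-05). Gadd45g (-3.10), Gadd45b (-2.13), Gadd45a (-1.42), Mbd3 (-0.89), Dnmt3b (-0.75) and the glycosylase gene Tdg (-0.61) also fell, and Mbd2, which encodes a reader of methylated DNA, rose by 1.05 (SE 0.14, adjusted p = 0.00064). The de novo methyltransferase gene Dnmt3a was at 13.67 ± 0.13 and 14.22 ± 0.97 (n = 3 each) and did not pass (0.54, SE 0.44, adjusted p = 0.326). After the length correction it passed with 0.88 (adjusted p = 0.0223), and so did Zbtb4 with 0.78 (0.47 before; adjusted p = 0.0051). Neither Dnmt3l (0.12), Mecp2 (-0.12), Mbd1 (0.28), Mbd4 (-0.34), Mbd5 (-0.41), Mbd6 (-0.28), Zbtb33 (0.38) nor Zbtb38 (0.32) passed. Of the dioxygenase genes that oxidise methylcytosine, Tet1 (-0.27, SE 0.45), Tet2 (-1.47, SE 0.69) and Tet3 (0.03, SE 0.31) did not pass.

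In all, 1 of the 22 DNA methylation genes rose and 8 fell (the same counts adjusted over the list alone), and the list did not pass against all other genes (median -0.31, camera adjusted p = 0.159). P18 replicate 1 decides much of this. It held higher length-corrected values than the mean of the other P18 libraries for 20 of the 22 genes, by a median of 0.52. Without it 2 genes rose and 15 fell, and the list passed with a median of -0.64 (camera adjusted p = 0.018). Tet1 then had -0.83 (adjusted p = 0.00062), Tet2 -2.35 (adjusted p = 3.7e-06), Tet3 -0.35 (adjusted p = 0.0155), Mecp2 -0.53 (adjusted p = 0.0036), Mbd4 -0.50 (0.0381), Mbd5 -0.81 (0.0011), Mbd6 -0.64 (0.00089) and Zbtb33 0.67 (0.00018). The calls of Dnmt3b and Tdg were lost without P2 replicate 2 (adjusted p = 0.0568 and 0.0587), and that of Tdg also without P18 replicate 3 (0.0545). Scaling to the linear total gave 1 higher and 13 lower (median -0.94), with Dnmt3l at -0.51.

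**Figure D3:**
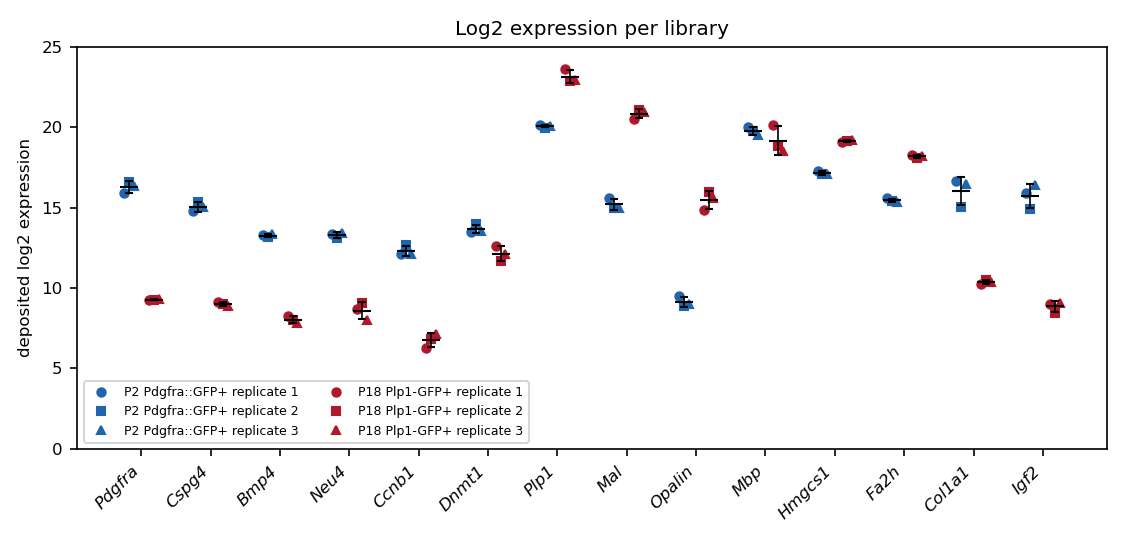
Deposited log2 expression (y axis) of 14 genes in each of the 3 P2 libraries (blue) and 3 P18 libraries (red). Symbols mark the replicates, horizontal ticks the group mean and bars the SD (n = 3); Pdgfra lies at 15.90 to 16.62 against 9.26 to 9.29, Opalin is higher at P18 in every library, and the P18 values of Mbp span 18.50 to 20.17, with replicate 1 the highest.

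Chromatin and transcription factor lists went both ways. Of 23 histone deacetylases and repressive histone methyltransferases, 5 rose and 10 fell (the same counts adjusted over the list alone; median -0.52, camera adjusted p = 0.329), and 3 rose and 16 fell under scaling to the linear total (median -1.15). Hdac11 rose most (2.71, SE 0.16), with Ezh1 (2.03), Hdac9 (1.45), Hdac5 (1.29) and Hdac10 (0.46), while Suv39h2 (-2.01), the H3K27 methyltransferase gene Ezh2 (-1.37) and Hdac2 (-1.02) fell. Of 13 lineage transcription factors and cofactors, 1 rose and 5 fell (0 and 4 adjusted over the list alone; median -0.16, camera adjusted p = 0.295), and Sox10 (-0.16) and Olig1 (0.52) did not pass. Nkx2-2 (-1.91) and Nfatc2 (-1.80) fell. The count of falls was 3 without P2 replicate 1, P2 replicate 2 or P18 replicate 3, and 7 without P18 replicate 1, where 2 rose. Scaling to the linear total gave 9 falls and no rise in this list (median -0.80). Smarca4 (-1.07) lost its call without any 1 library except P18 replicate 1 (adjusted p = 0.0911 to 0.126), and Zfp536 (1.49), the 1 rise, without any 1 of the P2 libraries or P18 replicate 3 (adjusted p = 0.0859 to 0.140), and no gene of the list rose under upper quartile, median-ratio or linear total scaling or without the 50 most abundant genes.

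Genes that hold back differentiation fell without exception among those tested: 18 of 18 inhibitors of oligodendrocyte differentiation were lower, also adjusted over the list alone (median -3.32, camera adjusted p = 4.0e-08, adjusted p = 0.0878 with an estimated correlation). Lingo1 fell by 5.18, Sox9 by 4.72 and Sox11 by 4.60 on the log2 scale. Of 19 Notch and Wnt pathway genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone; median -1.36, camera adjusted p = 3.0e-05, adjusted p = 0.181 with an estimated correlation), with Dll3 (-5.75), Dkk3 (-3.57) and Fzd9 (-2.81) the largest falls. The rise was in Nkd1 (1.45, SE 0.19), which encodes an antagonist of Wnt signalling.

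Receptor genes for glutamate and GABA were mostly lower: 19 of 24 fell and 1 rose (20 and 1 adjusted over the list alone; median -2.11, camera adjusted p = 3.5e-07, adjusted p = 0.268 with an estimated correlation). Grik3 (-4.36), Gria3 (-4.02) and Gabrg1 (-3.66) fell most. The single rise, Grin2c (0.46), lost its call without any 1 library except P18 replicate 1 (adjusted p = 0.0792 to 0.1435) and was at -0.18 under scaling to the linear total. Glycolysis and lactate transport genes split, 4 higher and 8 lower of 19 (5 and 9 adjusted over the list alone; median -0.23, camera adjusted p = 0.406). Ldha (-2.58), Hk2 (-2.03) and Pfkm (-1.71) fell and Eno2 (1.97) rose. Without P18 replicate 1, 8 rose and 9 fell, and under scaling to the linear total 2 and 11 (median -0.86).

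Of 28 splicing regulators 13 fell and 2 rose (the same adjusted over the list alone; median -0.55, camera adjusted p = 0.00354, adjusted p = 0.268 with an estimated correlation). Hnrnpd (-2.66), Hnrnpa1 (-2.53) and Ptbp1 (-2.03) fell and Mbnl2 (2.80, SE 0.14) rose, and 1 gene rose when P2 replicate 1 or P2 replicate 2 was left out. Under scaling to the linear total 23 splicing regulators fell and 1 rose (median -1.18). Of 21 imprinted genes 12 fell and 2 rose (13 and 4 adjusted over the list alone; median -1.16, camera adjusted p = 0.00354, adjusted p = 0.181 with an estimated correlation), and 4 rose without P18 replicate 1. Scaling to the linear total gave 15 falls and 1 rise of imprinted genes (median -1.79). Besides H19, Igf2 (chromosome 7, 142650768 to 142658804) fell from 15.74 ± 0.75 to 8.86 ± 0.34 (n = 3 each; adjusted p = 1.1e-05) and Nnat by 4.19, while Sgce (1.63) and Snrpn (0.89) rose. Among the P2 libraries, replicate 2 was lowest for both Igf2 and H19, by 1.23 and 1.56 below the mean of replicates 1 and 3 on the log2 scale. The mural cell and fibroblast markers were also lower in it.

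Antigen presentation and interferon genes did not pass against all other genes (7 higher and 3 lower of 15, the same adjusted over the list alone; median 0.55, and -0.09 with 2 higher and 5 lower under scaling to the linear total; camera adjusted p = 0.356). Ifit3 (1.70) and Bst2 (1.54) rose and Ifitm3 (-2.15) fell. Without P18 replicate 3, 4 rose, and without P18 replicate 1, 5 fell. The call of H2-D1 (0.91) was lost without any 1 library except P18 replicate 1 (adjusted p = 0.0676 to 0.109).

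**Figure D4:**
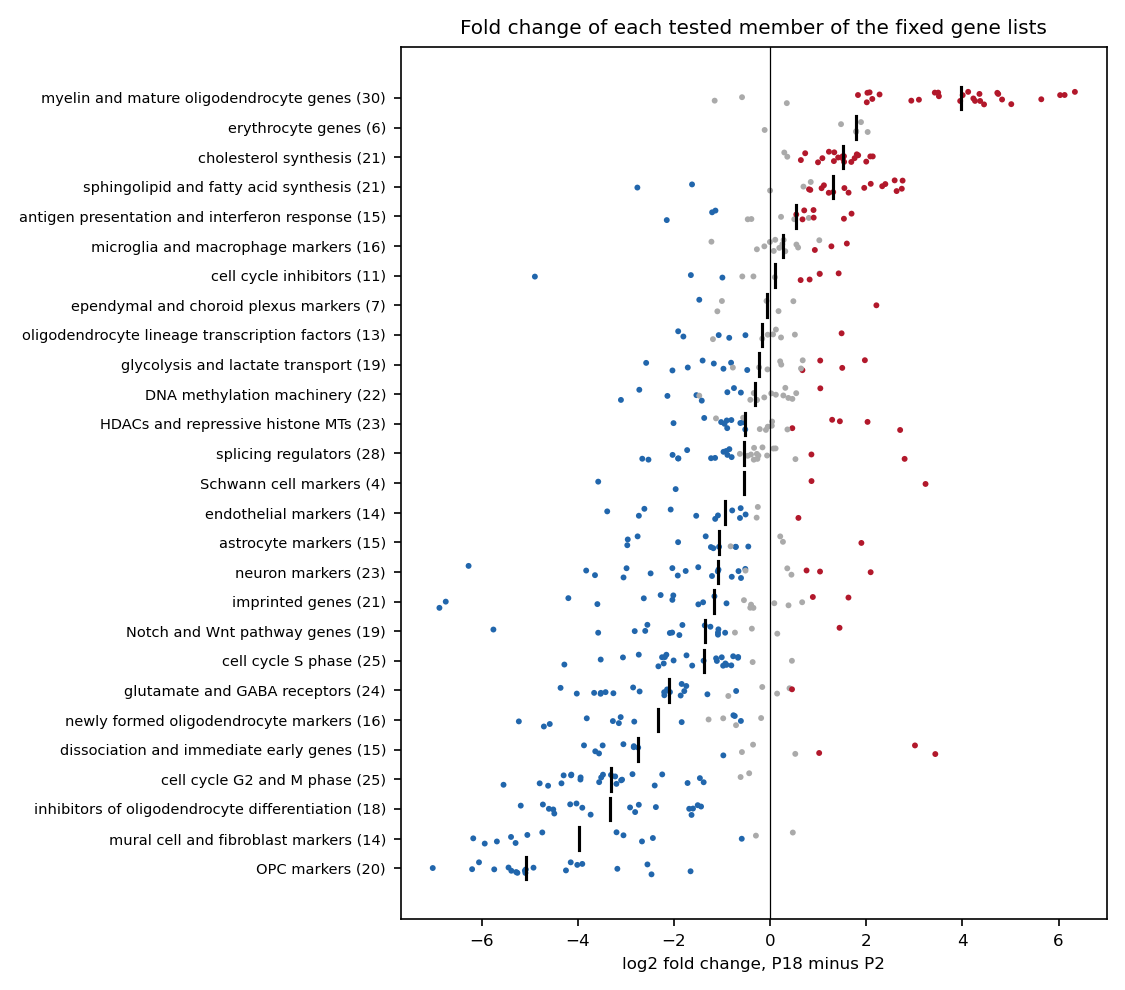
Log2 fold change (P18 minus P2, x axis) of every tested member of the 27 gene lists fixed in advance, with the number tested in brackets and the list median as a black bar. Red and blue points passed the limma test as higher or lower and grey points did not; list medians run from -5.08 for OPC markers to 3.98 for myelin and mature oligodendrocyte genes.

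Markers of other brain cells were examined for RNA of those cells in the sorted fractions, and most were lower at P18. Whether a marker came from other cells or from the lineage itself was not tested. Of 14 mural cell and fibroblast markers 12 fell and none rose (12 and 1 adjusted over the list alone; median -3.96, camera adjusted p = 1.0e-05, adjusted p = 0.268 with an estimated correlation). The most abundant at P2 was Col1a2 (840 ppm, and 12.5 at P18), and at P18 Col3a1 (15.4 ppm, and 671 at P2). Col1a1 (-5.68, SE 0.39), Lum (-6.17) and Dcn (-5.93) fell, and Acta2 (0.47) and Tagln (-0.29) did not pass. P2 replicate 2 held less of these markers than the other P2 libraries, by a median of 1.16 on the log2 scale, in 13 of the 14. Without P18 replicate 1, 1 marker passed as higher. Of 14 endothelial markers 11 fell and 1 rose (the same adjusted over the list alone; median -0.93, camera adjusted p = 0.00105, adjusted p = 0.268 with an estimated correlation), with Cdh5 (-3.39) and Cldn5 (-2.61), and Itm2a was the most abundant (113 and 10.9 ppm). Under scaling to the linear total 13 endothelial markers fell and none rose (median -1.57). The rise, Ly6a (0.59), was lost without P2 replicate 2, P2 replicate 3, P18 replicate 2 or P18 replicate 3 (adjusted p = 0.0862 to 0.109) and was at -0.04 under scaling to the linear total and -0.32 with the mean of its transcripts.

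Of 23 neuron markers 17 fell and 3 rose (18 and 4 adjusted over the list alone; median -1.09, camera adjusted p = 0.000745, adjusted p = 0.181 with an estimated correlation). Under scaling to the linear total 18 neuron markers fell and 1 rose (median -1.72). Gap43 (-6.27), Neurod1 (-3.82) and Nefm (-3.64) fell. Map2 was the most abundant at P2 (499 ppm, and 42.1 at P18), and Tubb3 at P18 (206 ppm, and 69.9 at P2). With the deposited scaling, which differs from these shares of the linear total, the log2 fold change of Tubb3 was 2.09 (SE 0.36). Of 15 astrocyte markers 11 fell and 1 rose (12 and 1 adjusted over the list alone; median -1.06, camera adjusted p = 0.00672, adjusted p = 0.268 with an estimated correlation), with Gjb6 (-2.97), Gja1 (-2.96) and F3 (-2.75) lower and Agt (1.90) higher, and 2 rose without P18 replicate 1. The median of the astrocyte markers was -1.695 under scaling to the linear total. Slc1a3 was the most abundant in both groups (158 and 61.8 ppm).

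Few microglial and macrophage markers changed: 3 of 16 rose and none fell (2 and 0 adjusted over the list alone; median 0.27, and -0.37 with 2 higher and 2 lower under scaling to the linear total; camera adjusted p = 0.283). P2ry12 (1.60) and Tyrobp (1.28) rose. Ctss (0.93) lost its call without any 1 library except P18 replicate 1 (adjusted p = 0.0671 to 0.131), and 7 markers rose without P18 replicate 1. One fell when P2 replicate 2 or P18 replicate 3 was left out. The most abundant were Tmem119 at P2 (14.9 ppm) and Csf1r at P18 (11.3 ppm). No erythrocyte gene of 6 passed the limma test, also adjusted over the list alone, while 3 had an unadjusted p under 0.05 (median 1.79, camera adjusted p = 0.258, and 1.16 and 0.0433 under scaling to the linear total, where 1 fell), but without P18 replicate 1, 5 rose and the list passed (median 2.69, camera adjusted p = 0.021). Hbb-b2 was at 6.31 and 22.8 ppm and Alas2 at 7.25 and 16.1.

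Of 7 ependymal and choroid plexus markers Foxj1 rose (2.21) and Clic6 fell (-1.47), also adjusted over the list alone (camera adjusted p = 0.856), and 2 fell without P2 replicate 3 or P18 replicate 3, and 4 under scaling to the linear total. Ttr was the most abundant in both groups (81.0 and 24.8 ppm). The 4 tested Schwann cell markers split, also adjusted over the list alone, with Cdh19 (3.23) and Prx (0.86) higher and Egr2 (-3.57) and Ngfr (-1.96) lower (camera adjusted p = 0.873). Ngfr was at 10.2 ppm at P2 and Cdh19 at 34.1 at P18. Of 15 dissociation and immediate early genes 9 fell and 3 rose, the same adjusted over the list alone (median -2.74, camera adjusted p = 0.072, and 0.0369 without P2 replicate 2). Ier3 (-3.87), Nr4a1 (-3.63) and Ier2 (-3.56) fell, and the heat shock genes Hspa1b (3.44) and Hspa1a (3.01) and Jund (1.02) rose.

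By camera 16 of the 27 lists passed at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. By fry, which asks whether the genes of a list moved one way without comparing them with other genes, 20 lists passed, all 16 among them. The others were the antigen presentation and interferon genes (fry adjusted p = 0.0093), the dissociation and immediate early genes (0.0093), the lineage transcription factors and cofactors (0.0103) and the cell cycle inhibitors (0.0317), and in each of these lists members passed in both directions.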

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

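Across the 23 alternatives, every transcript as a row among them, the number of changed genes stayed within 1.5 times of 8453. Leaving out 1 library gave 6678 (without P2 replicate 2) to 11458 genes (without P18 replicate 1); each of the other exclusions lowered the number, as fewer samples do. Genes higher at P18 then numbered 3267 to 5906, genes lower 3392 to 5552, and genes changed at least 2-fold 4900 to 5921. Directions followed the scaling: library totals gave 1789 genes higher and 8184 lower, and leaving out the 50 most abundant genes 2636 higher, because both factors shift every gene by the same amount. Direction turned in 30 values of named genes, 2 of them past the threshold (Dnmt3l under library totals and Tet3 without P18 replicate 1). Library totals turned Dnmt3l to -0.51, Grin2c to -0.18, Ly6a to -0.0448, Dnmt3a to -0.0905, Tet3 to -0.61, Mbd1 to -0.358, Zbtb33 to -0.254, Zbtb4 to -0.170, Zbtb38 to -0.317, Csf1r to -0.352 and Myrf to -0.286. Leaving out the 50 most abundant genes turned Dnmt3l to -0.241, Tet3 to -0.337, Mbd1 to -0.0850, Zbtb38 to -0.0437, Csf1r to -0.0785 and Myrf to -0.0128. The length correction turned Dnmt3l to -0.0548, Tet1 to 0.0982 and Mecp2 to 0.221, quantile normalization Tet3 to -0.191, Mbd4 to 0.0338 and Myrf to -0.664, the upper quartile Tet3 to -0.00905, and the mean of its transcripts Ly6a to -0.32. With 1 library left out, values ran from without P18 replicate 1 to without P18 replicate 2: Tet1 -0.834 to 0.0850, Tet3 -0.35 to 0.26, Mecp2 -0.534 to 0.182 and Zbtb38 -0.451 to 1.08. Over all alternatives Tet3 lay between -0.61 and 0.37 (length correction); the cause was not tested. The camera direction, taken against all other genes, turned from down to up in 7 results of lists that passed neither before nor after. List medians need not follow that turn. For cell cycle inhibitors the median was -0.534 under library totals and 0.0181 to 0.178 with 1 library left out. For ependymal markers it was -0.708 and -0.266 to 0.0673. For Schwann cell markers it was -1.19 under library totals, -0.131 without a filter and -0.912 without the 50 most abundant genes. With the replicate block 7128 genes changed, and the dissociation and immediate early genes passed camera (adjusted p = 0.0246), as under quantile normalization (0.0252). The block ended the calls of Rbl2 (limma adjusted p = 0.0641), Smarca4 (0.0539), Zfp536 (0.061), Grin2c (0.1099) and Ly6a (0.0839). Samples that share a number did not deviate together (correlations across genes of -0.396, -0.133 and -0.145), and no sample correlated best with its own number. Over all alternatives, 2882 values of named genes kept their direction and side of the threshold, 67 dropped under it and 33 newly passed. Of the list results 576 stayed and 9 newly passed, 4 of them under quantile normalization, chosen after seeing the data. Pseudocounts of 0.1, 1 and 5 hardly moved a value (8453, 8453 and 8459 genes changed), and the filters leave each fold change as it was. Part of the unchanged values therefore comes from alternatives that could hardly differ. Quantile normalization set Plp1 to 0 by construction, since it ranks first in every library. The DESeq2 Wald test, voom and the legacy edgeR fit were not run because they need counts, and library quality weights did not converge and were not used. Depth is unknown, so what it limits cannot be stated.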

Other observations

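Of 16 gene families defined by their symbols, 3 passed camera, adjusted over the families; all families and tests in this part were chosen or written down after the data were seen. Of 81 cytosolic ribosomal protein genes, 24 fell and none rose at P18 (median log2 fold change -0.73, camera adjusted p = 0.00012, adjusted p = 0.924 with an estimated correlation). After the length correction 73 fell (median -0.97), and without P18 replicate 1, 37 fell and 1 rose (median -0.33). Under scaling to the linear total 77 ribosomal protein genes fell (median -1.37). Of 42 collagen genes 25 fell and 4 rose (median -1.61, camera adjusted p = 0.00057), and 7 rose without P18 replicate 1; under scaling to the linear total 32 fell and none rose (median -2.25). Col1a1, Col1a2 and Col3a1 among them are also in the list of mural cell and fibroblast markers, of which 12 of 14 fell (median -3.96). Of 19 subunit genes of the V-type proton pump 10 rose and none fell (median 0.71, camera adjusted p = 0.0482). Without P18 replicate 1, 15 rose and 1 fell, and scaling to the linear total brought the median to 0.07, with 3 higher and 4 lower. Neither collagens nor the pump genes passed with an estimated correlation (adjusted p = 0.924 for both). The other 13 families did not pass at the preset correlation. Without P18 replicate 1, 5 of them did. NADH dehydrogenase subunits (32 of 36 higher, against 3 with all libraries, camera adjusted p = 1.5e-05) and proteasome subunits (22 of 35, against 1, 0.0031) rose. Kinesins (26 of 36 lower, against 15, 0.0023), potassium channel alpha subunits (23 of 44, against 19, 0.0400) and semaphorins (15 of 20, against 8, 0.0400) fell. The families that rose have short transcripts (median 732 and 1512 bases) and those that fell long ones (4218 to 4983). The library left out is the one that stood apart with a trend on length. With all libraries and the length correction none of the 5 passed (camera adjusted p = 0.225 to 0.859), and 9 of 36 NADH dehydrogenase subunits were higher.

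P18 replicate 1 differed from the mean of the other P18 libraries with an SD of 0.673 (log2) across genes, against 0.303 between replicates 2 and 3. A trend with transcript length alone does not account for it: after the length correction the SD was 0.587, still 2.00 times the SD of 0.294 between replicates 2 and 3 after the same correction. Length may explain a part, since the difference correlated with it at rho = 0.495 over 14890 genes. Differences between libraries that did not stand apart correlated with it too (-0.44 for P2 replicate 1 minus 3, -0.31 for P18 replicate 2 minus 3). A rho does not measure the size of a trend. From the shortest to the longest transcripts, bin medians ran from -0.65 to 0.49 for replicate 1 and from 0.18 to -0.10 for P18 replicate 2 minus 3. A larger share of newly formed oligodendrocytes is another candidate explanation. After the correction 14 of their 16 markers were higher in replicate 1, by a median of 0.76, above 100% of 10000 random lists matched on mean expression. Most myelin and mature genes were lower (median -0.40, 7 of 30 higher, above 6.58% of such lists). The most abundant, Plp1, held more of the linear total in replicate 1, 9.32% against 4.94% and 5.51%. Mbp and Mobp were also higher there after the correction, by 1.68 and 0.70, so the myelin genes do not all go with this explanation. The DNA methylation genes also lay above 100% of such lists (median 0.52). That list was not chosen to mark a cell stage, so it cannot tell whether the shift is confined to 1 stage. The OPC markers lay above 78.1% (median 0.01, 10 of 20 higher). The random lists were drawn gene by gene and do not keep the correlation within a list, estimated at 0.55 for the newly formed markers. These percentiles can therefore be too extreme. Both explanations stay open.

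Igf2 and H19 fell by over 6 on the log2 scale, together with fibroblast genes such as Lum and Dcn. RNA of fibroblasts in the P2 libraries may explain this, since fibroblasts also express Pdgfra and a gate on it would not remove them. In P2 replicate 2, 13 of 14 mural cell and fibroblast markers were lower than in the other P2 libraries (median -1.16) while OPC markers were higher (median 0.40), and Igf2 (-1.23) and H19 (-1.56) went with the former, both within the lowest 0.637% of tested genes. The most abundant of these markers, none of which is in another list, reached 840 (Col1a2), 794 (Col1a1) and 671 (Col3a1) ppm at P2. Some markers of other cell types were also lowest in P2 replicate 2. There Gja1 was at 12.57 against 13.71 and 14.45, Tmem119 at 9.27 against 10.84 and 10.83, and Cdh5 at 10.87 against 11.59 and 12.02. Others, such as Slc1a3, Cldn5 and Map2, were not lowest there. The pattern therefore cannot tell RNA of fibroblasts from RNA of other cells. Of the 712 genes that fell at least 8-fold, 119 (16.7%) were over 0.5 lower in P2 replicate 2, against 4.16% of all tested genes. Genes over 0.5 higher there were not counted, and the genes compared were not matched on level or spread. Ccna2, which also fell over 8-fold, was at 12.85 there against 12.33 and 12.25 in the other P2 libraries. This excess therefore cannot be laid to fibroblast RNA. A loss of Igf2 and H19 within the lineage or with age was not tested and stays open, and 1 library excludes nothing.

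Mbp did not rise at P18 while 27 of 30 myelin genes did. A trend with transcript length is argued against, since the length-corrected log2 fold change was -0.73 (SE 0.44). Another choice of transcript row would not have made Mbp rise, since the highest of 8 Mbp rows was at -0.56 with no positive value. Rows of 1 gene share exons and the counting is not known, so these rows could hardly differ. They cannot decide on a cause in how reads were assigned to rows. Loss of transcripts carried into cell processes when cells are dissociated could lower Mbp. Of 5 other genes whose transcripts are described as carried there, 3 rose (Mobp 2.01, Car2 4.83, Padi2 1.05) and Kif1a (0.51) and Dync1li2 (-0.03) did not pass, which decides nothing. A difference between the stages themselves was not tested and stays open.

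The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 8453 genes and the highest of the others 0, so 1 division gave as many. Every other division puts libraries of both stages in each group, so the difference between stages widens the spread within groups. Few calls could arise there, and the 0 gives no support to the real division.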
